A study of Caulobacter vibrioides NA1000 with 9 samples.

How the data were processed

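The series holds 9 RNA sequencing libraries of Caulobacter crescentus NA1000, 3 of the wild type (WT), 3 of a strain without flgE (ΔflgE) and 3 of a strain without motB (ΔmotB). Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was treated with DNase, depleted of ribosomal RNA with a bacterial Ribo-Zero kit and made into libraries with a TruSeq kit that keeps the strand. The labels of all 9 libraries also read "TEX treated". What this treatment did is not given in the sources used here, and a treatment that acts on RNA ends would change which reads the flanks described below hold. The labels give each group its own strain name (FC764 for WT, YB6375 for ΔflgE and YB7377 for ΔmotB) and do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

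The authors deposited raw read counts per feature for the 9 libraries in 1 table, and its values are whole numbers that sum to a different total in each library. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.33, Bowtie2 and DESeq2 were used. The role of each tool, the counting program, the annotation, the genome build and the treatment of reads that map to several places are not given in the sources used here. The table has 3886 gene features, 200 RNA features and 46000 windows of up to 100 nt, most of which lie outside genes on their own strand. By the reference table described below, 701 windows begin inside a gene on the same strand. These were left out of the flanks and opposite-strand sums described below. Gene and RNA features carry running numbers, and the files do not pair these numbers with gene names. Each window carries its strand and position. A reference table of 4097 genes (assembly ASM2200v1) gave names, starts and ends. The strand of 3946 of these genes was assigned from the strand on which windows leave a gap over the gene, where the share of the gene covered by windows differed by more than 0.3 between strands. As a check of the shared coordinates, 3193 gaps whose first window starts directly after a reference gene were compared with the number of windows they should hold. Of these, 94.4% matched exactly. Gaps that start elsewhere were not part of this check.

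Named genes were therefore measured through windows. The upstream flank of a gene is the sum of same-strand windows that overlap the 100 nt before its start (3081 genes), and the downstream flank is the sum of those that overlap the 100 nt after its end (3064 genes). Reads on the opposite strand inside a gene were summed for 3769 genes. A flank holds leader, tail or read-through RNA and not the body of the gene, so reads of an upstream flank can belong to the preceding gene. Neighbouring genes can share windows: this holds for the downstream flank of flgE and the upstream flank of sciP, motB and CCNA_01643, pilA and cpaA, flgL and CCNA_00941, fljK and CCNA_01529, flgF and flgG, CCNA_00945 and flgD, and flgD and flgE. It also holds for CCNA_01529 and fljJ, flgH and CCNA_02146, flgB and flgC, cpaA and cpaB, cpaG and cpaH, and cpaI and cpaJ. The flagellin genes are paralogs, and their values are uncertain wherever reads map to more than 1 of them.

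Depth, as total counts, was 5044569, 4996403 and 6076961 in WT replicates 1 to 3, 5314793, 7105658 and 6063457 in ΔflgE, and 7838242, 5511072 and 7078041 in ΔmotB. Gene features took from 80.8% to 83.8% of the counts, RNA features from 5.60% to 8.16% and windows from 10.1% to 11.7%. Flanks held a mean of 94.3 reads per 100 nt and the strand opposite genes 3.55. The median flank had 8 counts per library, which limits the precision of flank values.

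Counts were tested with edgeR 4.0.16 (quasi-likelihood fit and test, all 9 libraries in 1 fit with the group as the only term, default low-count filter by group) in R 4.3.3. TMM factors came from gene and RNA features in every test, flanks included. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 within each kind of feature. After the filter 3919 gene and RNA features, 1517 upstream flanks, 2049 downstream flanks and 2199 sums of opposite-strand reads were tested, with biological coefficients of variation of 0.11, 0.14, 0.132 and 0.111. A flank with few reads passes this filter more readily where 1 group is high, so counts of rises among tested flanks of few reads are not free of the filter. Values are CPM, the library-scaled counts given by edgeR's cpm function with TMM factors, as mean ± SD of 3 libraries, and fold changes are on the log2 scale with standard errors (SE). Intervals are 95% confidence intervals. Where every library of a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. Fold changes of edgeR tests, with their SEs and 95% intervals, come from the edgeR fit and include the spread between libraries. Floors, and the intervals called counting intervals, cover counting error only. The same steps were tested on simulated counts for the ΔflgE comparison, with 200 features changed by 1.5, 2 or 4 times. They recovered 59.7%, 88.1% and 98.5% of changed features among 3919 gene and RNA features, 31.3%, 70.1% and 97.0% among 1517 upstream flanks, and 20.9%, 76.1% and 93.9% among 2049 downstream flanks, with 6 of 170, 6 of 138 and 7 of 134 calls false.

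Gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The use of flanks in place of gene features was not. The 21 lists covered Flp pilus genes, the flagellar switch and export apparatus, rod, ring and hook genes, flagellins, flagellin modification, flagellar regulators, the stator, chemotaxis, cell cycle regulators, DNA replication, cell division, holdfast, cyclic di-GMP, stalk and phosphate genes, the S-layer, ribosomal proteins, heat shock, the SOS response, general stress, TonB-dependent receptors, and respiration with ATP synthase. Lists were matched by gene symbol. Product descriptions were not used here, which left the list of TonB-dependent receptors empty, and ribosomal proteins were taken by the symbol stems rps, rpl and rpm, a rule set after the reference table was seen. Lists with at least 3 tested flanks were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. This gave 17 lists for upstream and 18 for downstream flanks. The rule for named genes takes flgE, motB and any called gene among the 3 nearest on each side, every tested pilus gene, the 8 largest called rises and 8 largest called falls against WT in which all libraries of the groups lie apart, and up to 3 called members of every other list by p. Between the mutants it takes the 5 largest rises and 5 largest falls.

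Alternatives were other scalings (RLE, upper quartile, library totals), DESeq2 1.42.0, limma voom, other low-count filters, a fit of the 6 libraries compared, the replicate number as a block, every library left out in turn, other thresholds, and, chosen after the data were seen, no RNA features, factors from the flanks themselves and other flank widths. Removal of ribosomal RNA alone was not run, because RNA features are not paired with names, and RNA features as a whole were left out in its place. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.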

Results

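RNA was sequenced from Caulobacter crescentus NA1000, an aquatic bacterium that divides into a stalked cell and a swarmer cell with a polar flagellum and pili. The 9 libraries fall into 3 groups of 3: the wild type (WT), ΔflgE, which lacks the gene of the flagellar hook protein, and ΔmotB, which lacks the gene of a stator protein that powers flagellar rotation. The title of the series is about pilus synthesis in flagellar mutants, so the comparisons ask which transcripts, those of pilus genes among them, differ between either mutant and WT. Total counts per library ran from 4996403 to 6076961 in WT, from 5314793 to 7105658 in ΔflgE and from 5511072 to 7838242 in ΔmotB. The deposited counts name no gene, so named genes are described by the reads next to them, called upstream and downstream flanks. Positions are those of the chromosome in assembly ASM2200v1.

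Reads from the deleted genes were looked at first. Opposite the flgE gene (1024495 to 1026270, plus strand), the WT libraries had 35, 42 and 63 antisense reads, the ΔmotB libraries 60, 51 and 60, and the ΔflgE libraries 0, 0 and 0. This is at least 54.0-fold lower in ΔflgE than in WT, with the floor of 3 counts taken over the group, and it passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 2.97e-12, 3 of 3 libraries lower). Opposite motB (1764656 to 1765552, minus strand), WT had 10, 7 and 9 reads, ΔflgE 7, 9 and 14, and ΔmotB 0, 0 and 0, at least 10.9-fold lower than WT, with too few reads to pass the filter for a test. Among gene features, gene1011 had 3211, 3365 and 3748 counts in WT and 1, 1 and 1 in ΔflgE, a WT to ΔflgE ratio of 3983 (95% counting interval 1363 to 19320). Feature gene1738 had 1039, 1013 and 1107 counts in WT and 0, 0 and 0 in ΔmotB, at least 1325-fold lower. Each loss was confined to 1 mutant: gene1011 had 5149, 3698 and 5050 counts in ΔmotB, and gene1738 had 842, 1070 and 963 in ΔflgE. Both are among the called gene features counted below. The files do not pair these feature numbers with gene names.

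In ΔflgE against WT, reads beside genes of the flagellar rod, rings and hook rose and reads beside most flagellin genes fell. The upstream flank of flgE, whose product forms the hook, rose 3.67-fold, from 27.8 ± 3.58 to 102 ± 8.62 CPM (SD, n = 3 and 3; log2 1.87, SE 0.16). The downstream flank of flgD, whose product is the scaffold for hook assembly, rose 4.57-fold, from 16.9 ± 1.70 to 77.2 ± 6.83 CPM (log2 2.19, SE 0.17). The flgD flank is part of the upstream flank of flgE, so both results share reads. The downstream flank of fljK, a gene of a major flagellin of the filament, fell by 2.80 on the log2 scale (SE 0.17), from 182 ± 21.2 to 26.0 ± 4.25 CPM, a 6.98-fold drop. By contrast the downstream flank of fljL, another flagellin gene directly before fljK, rose 3.31-fold, from 23.7 ± 0.443 to 78.5 ± 8.03 CPM (log2 1.73, SE 0.15). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (below: edgeR QL, BH) the adjusted p of these flanks was 4.22e-09, 5.90e-12, 2.67e-15 and 1.52e-10, and all 3 ΔflgE libraries lay beyond all 3 WT libraries, as in every flank called in any comparison here.

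**Figure D1:**
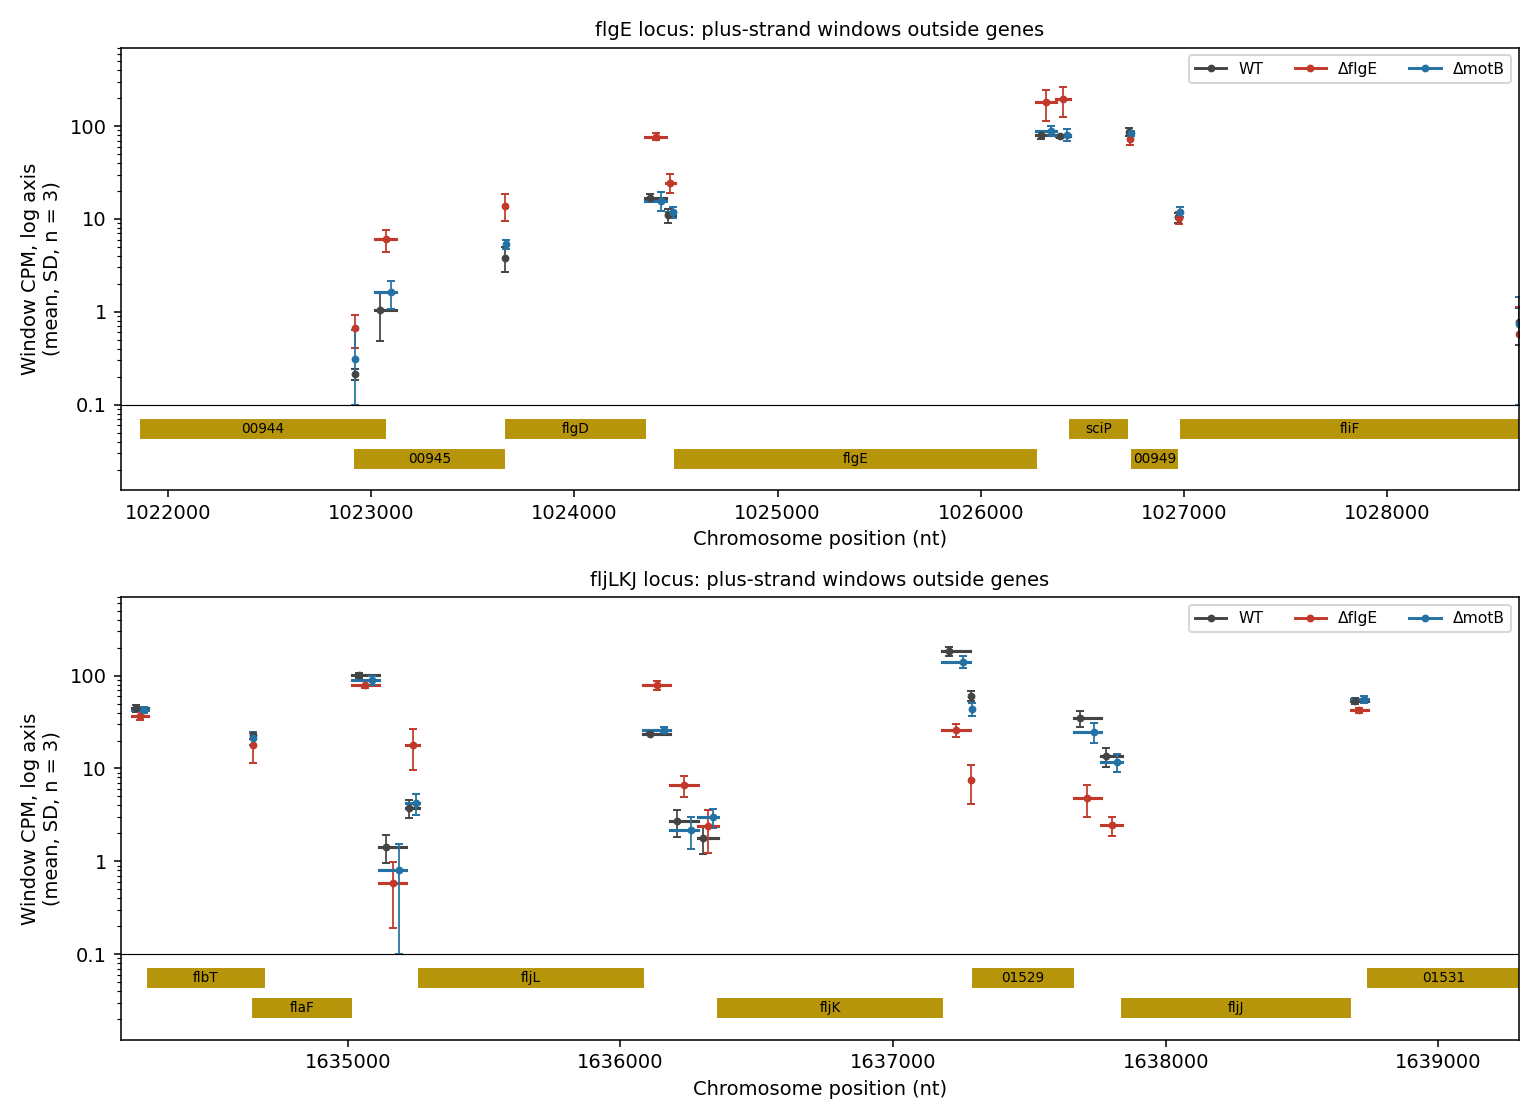
Mean CPM (log axis, whiskers SD, n = 3 libraries per group) in plus-strand windows, drawn at their chromosome positions (horizontal bars span each window), around flgE and around the flagellin genes fljL, fljK and fljJ. Yellow boxes are genes, those without a symbol shown by the number of their CCNA locus tag, and means under 0.1 CPM are not drawn. Windows that begin inside a gene are drawn too, such as those at 1022921 and 1023021 in CCNA_00944. In ΔflgE the window after flgD reached 77.2 CPM against 16.9 in WT, and the first window after fljK lay at 26.0 CPM against 182 in WT, while ΔmotB stood at 15.7 and 141.

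Of the rod, ring and hook genes, 3 of 4 tested upstream flanks (flgD, flgE and flgG) and 6 of 8 tested downstream flanks (flgD, flgE, flgF, flgH, flgL and flbY) rose in ΔflgE, and adjusted over the list alone the counts were again 3 and 6. Some of these flanks share windows, so the 12 tested flanks are 9 separate stretches, of which 7 rose. The low-count filter kept 4 of 11 upstream and 8 of 11 downstream flanks of the list. Flanks of few reads, such as those of flbY and flgH, pass it more readily where ΔflgE is high. These shares are therefore not free of the filter, here or against ΔmotB. With no low-count filter camera called the list on both sides too. The list as a whole moved up in camera (BH-adjusted p = 1.25e-08 upstream and 1.04e-09 downstream) and kept its call with an estimated correlation (adjusted p = 0.0128 and 0.00884). The genes lie at several loci. The flank shared by flgL, a gene of a hook-filament junction protein, and CCNA_00941 rose 2.79-fold (log2 1.48, SE 0.20; edgeR QL, BH-adjusted p = 3.61e-06 as flgL). The window between flgB and flgC, genes of rod proteins, and the downstream flank of flgC were not called, with log2 values of -0.13 and -0.46. Flanks at the other loci held few reads. Downstream of flbY they went from 0.620 to 3.36 CPM (log2 2.38, SE 0.49), in the window shared by flgF and flgG from 1.53 to 5.14 CPM (log2 1.68, SE 0.37), and downstream of flgH from 0.861 to 2.97 CPM (log2 1.77, SE 0.46). Their edgeR QL, BH-adjusted p was 0.00304 for flbY, 0.00751 as flgF, 0.0172 as flgG and 0.0474 for flgH. The flbY call was lost without ΔflgE replicate 2 (adjusted p = 0.0622) and the flgF call without WT replicate 1 or 2 or ΔflgE replicate 3 (0.0956, 0.103 and 0.0932). The flgG call was lost without those and without ΔflgE replicate 2 (0.121, 0.15, 0.156 and 0.0619), and the flgH call without any WT replicate, ΔflgE replicate 1 or ΔmotB replicate 2 (0.0561, 0.285, 0.332, 0.411 and 0.0592).

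Flagellin genes, whose products build the filament, went in both directions in ΔflgE. Among 6 tested upstream flanks 1 rose (fljL) and 2 fell (fljJ and fljM), and among 5 tested downstream flanks 1 rose (fljL) and 3 fell (fljK, fljM and fljO). Adjusted over the list alone, 2 upstream flanks rose and 4 fell, and 1 downstream flank rose and 4 fell. Upstream of fljJ reads fell from 48.2 ± 9.48 to 7.21 ± 2.20 CPM (log2 -2.72, SE 0.22; edgeR QL, BH-adjusted p = 2.30e-09) and the downstream flank of fljO from 9.91 ± 1.42 to 2.25 ± 0.660 CPM (log2 -2.10, SE 0.27; 1.61e-06). The downstream flank of fljM fell by 1.71 on the log2 scale (SE 0.24; edgeR QL, BH-adjusted p = 6.64e-06). The upstream flank of fljL rose to 18.6 ± 8.10 CPM from 5.16 ± 0.891 (log2 1.84, SE 0.29; edgeR QL, BH-adjusted p = 0.000182), but with windows up to 200 nt before the gene the log2 value was -0.10. The list was called down for downstream flanks in camera (BH-adjusted p = 0.000838), a call lost with an estimated correlation (adjusted p = 0.159 with an estimated correlation), and was not called for upstream flanks (BH-adjusted p = 0.217), where the number of called lists went from 1 to 2, with flagellins added, once ΔflgE replicate 1 was left out. The flanks of CCNA_01529, a gene without a symbol between fljK and fljJ, share windows with the downstream flank of fljK and the upstream flank of fljJ and fell with them, by 2.85 upstream and 2.83 downstream on the log2 scale (edgeR QL, BH-adjusted p = 3.99e-12 and 2.02e-11).

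**Figure D2:**
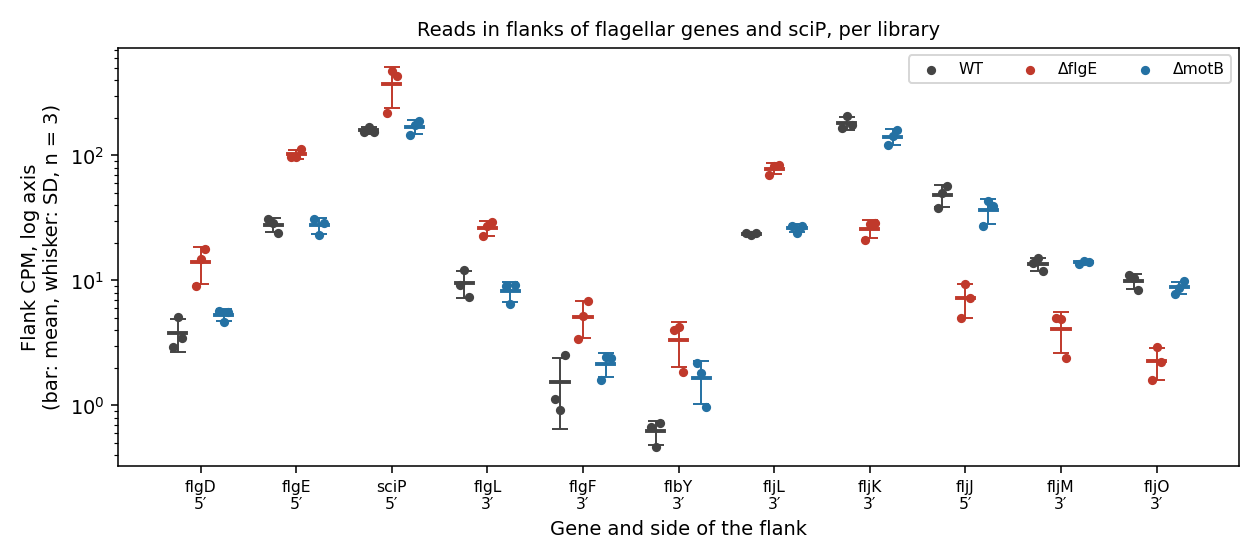
CPM of each library (points, log axis) with the mean (bar) and SD (whisker) of 3 libraries per group, for 1 flank (5′, upstream; 3′, downstream) of 10 flagellar genes and of sciP. The ΔflgE libraries lay above all WT libraries for flgD, flgE, sciP, flgL, flgF, flbY and fljL, at 96.6 to 112 CPM against 23.8 to 30.7 in WT for flgE, and below them for fljK, fljJ, fljM and fljO.

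Other named flanks in ΔflgE lay next to flagellar genes or had no symbol. Upstream of sciP, which follows flgE and whose product holds back the cell cycle regulator CtrA, reads rose from 159 ± 9.56 to 376 ± 137 CPM (log2 1.24, SE 0.19; edgeR QL, BH-adjusted p = 0.000144). It shares its windows with the downstream flank of flgE (log2 1.16, SE 0.19; 7.43e-05). CCNA_00945, before flgD, rose downstream (log2 1.88) in the window that is also the upstream flank of flgD, and CCNA_02146 rose upstream, in a flank that contains the downstream flank of flgH (log2 1.99, SE 0.38; edgeR QL, BH-adjusted p = 0.00301, or 0.0866 without WT replicate 3). Downstream of CCNA_02257 reads rose from 28.1 ± 2.45 to 88.5 ± 18.6 CPM (log2 1.66, SE 0.17; edgeR QL, BH-adjusted p = 6.42e-09). Downstream flanks of CCNA_00972, CCNA_02061 and CCNA_03099 fell by 1.27, 1.25 and 1.28 on the log2 scale (edgeR QL, BH-adjusted p = 0.00188, 0.00158 and 0.00304). The 0.05 threshold was also passed by the downstream flanks of CCNA_00620 (log2 -1.44; 0.0335) and CCNA_01549 (log2 1.73; 0.0335), and both calls were lost without any 1 of the WT replicates or of ΔflgE replicates 1 and 2, with adjusted p up to 0.291 and 0.285.

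Tested flanks of flagellar genes that act earlier in assembly were not called in ΔflgE. Among switch and export genes 0 of 7 upstream and 0 of 7 downstream flanks were called (adjusted over the list alone, 1 upstream flank fell; camera BH-adjusted p = 0.99 and 0.993), with the upstream flank of fliF, the gene of the membrane ring, at 10.4 ± 1.30 CPM in WT and 10.3 ± 1.47 in ΔflgE. Flagellar regulators, among them flbD and flbT, had 0 of 6 and 0 of 9 flanks called, the same adjusted over the list alone (camera BH-adjusted p = 0.949 and 0.993). Upstream of flbT there were 46.3 CPM in WT and 38.7 in ΔflgE (log2 -0.26). Over all flanks, 7 upstream rose and 3 fell among 1517 tested (7 and 6 without ΔflgE replicate 3), and 11 downstream rose and 10 fell among 2049 (7 and 8 without WT replicate 1, 7 and 9 without WT replicate 2). Of 3919 gene and RNA features, 19 rose and 23 fell, 26 of the 42 by more than 2-fold. The largest rise was that of gene1618, from 5440 ± 361 to 29074 ± 4858 CPM (log2 2.42, SE 0.13; edgeR QL, BH-adjusted p = 4.06e-07). All 42 had groups that did not overlap, which held for 19.9% of all tested features, against the 10% that chance gives. The median upstream flank shifted by -0.12 on the log2 scale in ΔflgE (-0.05 without ΔflgE replicate 1, -0.19 without replicate 2), and upstream values contain that shift. With no low-count filter 8 upstream flanks rose and 10 fell, and with a filter at 10 CPM 4 rose and 2 fell.

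No tested flank of a pilus gene was called in either mutant. The bodies of pilus genes could be tested only as unnamed gene features. Whether any of them is among the called features was not worked out here. The upstream flank of pilA, the gene of the major pilin (3198523 to 3198702, minus strand), had 17.5 ± 2.78 CPM in WT, 15.2 ± 5.45 in ΔflgE and 18.4 ± 3.20 in ΔmotB (SD, n = 3 each). The log2 difference from WT was -0.20 (95% interval -0.66 to 0.26) in ΔflgE and 0.06 (-0.39 to 0.52) in ΔmotB (edgeR QL, BH-adjusted p = 0.826 and 0.99). Its downstream flank, which overlaps the upstream flank of cpaA, had 6.06 ± 0.246 CPM in WT, 4.75 ± 1.40 in ΔflgE and 5.76 ± 0.807 in ΔmotB. The cpa genes, which encode the machinery of Flp pilus assembly, were tested through upstream flanks of cpaA, cpaB, cpaH and cpaJ and downstream flanks of cpaA, cpaG, cpaH, cpaI, cpaK and cpaL. Some of these share windows, so the 12 flanks are 8 separate stretches. Log2 values over all pilus flanks ran from -0.34 to 0.49 in ΔflgE and from -0.21 to 0.45 in ΔmotB. edgeR called 0 of 5 upstream and 0 of 7 downstream flanks in either mutant, 0 had an unadjusted p under 0.05, and DESeq2 and limma voom called 0, as did edgeR adjusted over the list alone. In camera the list had BH-adjusted p of 0.936 and 0.993 in ΔflgE and 0.914 and 0.948 in ΔmotB (upstream and downstream). The intervals leave open changes of the pilA flank within their bounds, a flank is not the body of the transcript, and without ΔflgE replicate 1 the pilA difference in ΔflgE was 0.04.

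**Figure D3:**
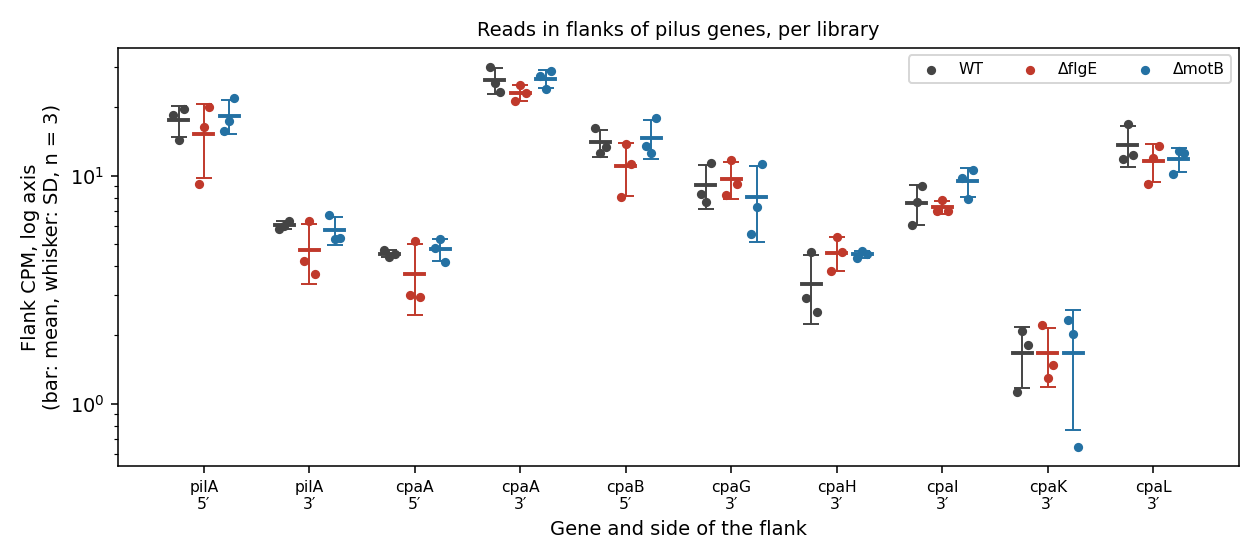
CPM of each library (points, log axis) with the mean (bar) and SD (whisker) of 3 libraries per group, for tested flanks (5′, upstream; 3′, downstream) of pilus genes. For the upstream flank of pilA the libraries lay at 14.4 to 19.7 CPM in WT, 9.23 to 19.9 in ΔflgE and 15.7 to 21.9 in ΔmotB.

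In ΔmotB against WT few flanks of named genes were called, and none of them rose. The window after motB, which is also the upstream flank of CCNA_01643, fell from 31.2 ± 3.37 to 14.7 ± 0.392 CPM (log2 -1.09, SE 0.18, n = 3 and 3). The downstream flank of rcdA, whose product helps the protease ClpXP degrade CtrA, fell from 52.9 ± 7.48 to 29.7 ± 0.828 CPM (log2 -0.84, SE 0.15). The downstream flank of CCNA_00972 fell from 10.2 ± 1.11 to 4.18 ± 1.30 CPM (log2 -1.30, SE 0.25). Flanks of flgE and fljK were not called. Upstream of flgE there were 27.6 ± 4.18 CPM (log2 -0.002). Downstream of fljK there were 141 CPM, with ΔmotB libraries at 120 to 160, below all WT libraries at 165 to 206. In ΔflgE the window after motB was not called (log2 -0.55), but it was without ΔflgE replicate 3 (log2 -0.73; edgeR QL, BH-adjusted p = 0.0423). The edgeR QL, BH-adjusted p in ΔmotB was 0.000969 for motB (0.00375 as the upstream flank of CCNA_01643, or 0.0567 without WT replicate 2), 0.00387 for rcdA and 0.00397 for CCNA_00972.

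Other downstream flanks that fell in ΔmotB were those of CCNA_01609, CCNA_00620, CCNA_01927, CCNA_02563 and CCNA_02616, with log2 values of -1.73, -1.51, -1.31, -1.06 and -0.93 (edgeR QL, BH-adjusted p = 0.0271, 0.032, 0.005, 0.0142 and 0.0197). Each of these calls was lost when WT replicate 2 was left out (adjusted p = 0.0703, 0.255, 0.056, 0.142 and 0.0703). All but that of CCNA_01927 were also lost without ΔmotB replicate 1 (0.115, 0.268, 0.169 and 0.185) or replicate 2 (0.221, 0.15, 0.0533 and 0.11). Without WT replicate 1 the calls of CCNA_01609, CCNA_00620 and CCNA_02616 were lost (0.482, 0.0821 and 0.15), as they were without ΔflgE replicate 2 (0.0661, 0.0651 and 0.0651), and that of CCNA_00620 was lost without WT replicate 3 (0.112). In all 0 upstream flanks rose and 1 fell, and 0 downstream flanks rose and 10 fell. At an unadjusted p under 0.05 in edgeR, 41 upstream and 49 downstream flanks were higher, DESeq2 called 0 and 1 rises, and limma voom 0 and 0. Of gene features 1 rose and 15 fell, 5 of the 16 by more than 2-fold. The one that rose, gene179, went from 131 ± 14.8 to 222 ± 2.99 CPM (log2 0.76, SE 0.08; edgeR QL, BH-adjusted p = 0.00177). All 16 had groups that did not overlap, as did 19.1% of all tested features (10% by chance).

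Flagellar lists were not called in ΔmotB. In camera, 0 of 17 upstream and 0 of 18 downstream lists passed, 1 on each side had an unadjusted p under 0.05 (ribosomal proteins), and 0 did with an estimated correlation. Without ΔmotB replicate 3 the ribosomal list was called on the downstream side. Rod, ring and hook genes had 0 of 4 upstream and 0 of 8 downstream flanks called (camera BH-adjusted p = 0.342 and 0.505), and flagellins 0 of 6 and 0 of 5 (0.984 and 0.995), in both cases also adjusted over the list alone. Of the rod, ring and hook flanks, 3 upstream were higher than in WT and 1 lower, and 5 downstream were higher and 3 lower (camera, unadjusted p = 0.0555 and 0.0561). Switch and export genes had 0 of 7 and 0 of 7 (0.914 and 0.995), with 1 upstream flank falling when adjusted over the list alone, and flagellar regulators 0 of 6 and 0 of 9, the same over the list alone (0.914 and 0.995). The stator list had 2 tested downstream flanks, too few for camera: motB fell, and motA had 18.1 CPM in WT and 17.3 in ΔmotB. The count of changed gene and RNA features depended on the test and on single libraries: it was 52 with DESeq2, 28 without ΔflgE replicate 1 and 10 without WT replicate 1. Downstream flanks went from 10 to 5 without WT replicate 1, to 4 without WT replicate 2 or ΔmotB replicate 1 or 2, and to 19 without ΔmotB replicate 3, and upstream flanks from 1 to between 0 (without WT replicate 2) and 7 (without ΔflgE replicate 1).

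The mutants were also compared directly, a test that uses no WT library in the contrast. At least 1 flank each of the hook genes flgD and flgE and of flgL was higher, and of fljJ, fljK, fljM, fljN and fljO lower, in ΔflgE than in ΔmotB. The upstream flank of flgE stood at 102 ± 8.62 CPM in ΔflgE and 27.6 ± 4.18 in ΔmotB (3.67-fold, log2 1.88, SE 0.16). The downstream flank of flgD, which is part of that flgE flank and shares its reads, stood at 77.2 ± 6.83 and 15.7 ± 3.58 CPM (4.85-fold, log2 2.28). The downstream flank of fljK stood at 26.0 ± 4.25 and 141 CPM (libraries 120 to 160; log2 -2.44), and that of fljL at 78.5 ± 8.03 and 26.2 ± 1.94 CPM (log2 1.58). The edgeR QL, BH-adjusted p was 4.41e-09, 1.15e-12, 1.57e-13 and 1.13e-09, with n = 3 and 3 and groups that did not overlap.

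Among rod, ring and hook genes 2 of 4 upstream and 3 of 8 downstream flanks were called higher in ΔflgE than in ΔmotB (3 and 6 adjusted over the list alone), and camera called the list (BH-adjusted p = 1.06e-05 and 3.65e-07; adjusted p = 0.0385 and 0.0203 with an estimated correlation). Among flagellins 1 of 6 upstream flanks was higher and 3 were lower, and 1 of 5 downstream flanks was higher and 3 were lower. Adjusted over the list alone these counts were 2 and 4 upstream and 1 and 4 downstream. Camera called the downstream flagellin list (BH-adjusted p = 7.21e-05; adjusted p = 0.0904 with an estimated correlation) and not the upstream one (BH-adjusted p = 0.17), although without ΔflgE replicate 1 it did, and without ΔflgE replicate 2 it called cell cycle regulators upstream. Pilus flanks had 0 of 5 and 0 of 7 called in edgeR, 0 with an unadjusted p under 0.05, and 0 adjusted over the list alone (camera BH-adjusted p = 0.623 and 0.788). Of gene and RNA features 20 were higher and 16 lower in ΔflgE (19 and 13 with RNA features left out, 37 and 15 without ΔmotB replicate 3), 24 of the 36 by more than 2-fold, all with groups that did not overlap, as did 13.6% of all tested features (10% by chance). Of upstream flanks 6 were higher and 5 lower, or 8 and 4 with factors from the flanks themselves and 6 and 10 without ΔflgE replicate 2. The median upstream flank shifted by -0.14 on the log2 scale (-0.05 without ΔflgE replicate 1). Of downstream flanks 6 were higher and 7 lower, or 14 and 7 without ΔmotB replicate 3.

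Both mutants were compared with the same WT libraries, and the responses overlapped in falls. Of 3919 gene and RNA features, 9 fell in both mutants, against 0.088 for independent lists, and 0 rose in both, against 0.00485. The files give no names for these 9. Among flanks, the downstream ones of CCNA_00972 and CCNA_00620 fell in both, with log2 values of -1.27 and -1.44 in ΔflgE and -1.30 and -1.51 in ΔmotB (edgeR QL, BH-adjusted p = 0.00188 and 0.0335, then 0.00397 and 0.032). The CCNA_00620 calls were lost in both mutants without any 1 of the WT replicates (adjusted p up to 0.291 and 0.255). With unchanged groups simulated against shared controls, a mean of 0.04 and at most 1 feature were called in both over 50 simulations. edgeR called 0 features in opposite directions, as did DESeq2 and limma voom, which called 0 in both up and 17 and 9 in both down. At an unadjusted p under 0.05, 58 features were higher in both, 86 lower in both and 3 opposite. Across features, which are not independent replicates, fold changes of the comparisons had a correlation of 0.564, against 0.463 to 0.554 in the simulations, and a covariance of 0.0374, against a simulated mean of 0.0187 (0.0165 to 0.0213), a difference of 0.0188, with 2 features beyond 5 on the log2 scale left out. The simulations hold the spread between libraries of a group, but no deviation common to the 3 WT libraries. The 3 WT libraries are too few to split, so part of the excess may still come from such a deviation in the shared controls.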

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

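The tests of the 3 patterns below and the use of flanks and opposite-strand reads were chosen after the data were seen, the test for stretches far from flgE was replaced more than once after values were seen, and the counts of other splits of the libraries were set out before their results were.

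Named flanks that passed the test between the mutants are listed here, and they were picked because they differ. Higher in ΔflgE than in ΔmotB were the upstream flanks of fljL (log2 1.88), flgE (1.88), CCNA_00941 (1.66), CCNA_02146 (1.61) and flgD (1.38). Of downstream flanks, those of flgD (2.28), CCNA_02257 (1.67), flgL (1.66), fljL (1.58) and CCNA_00945 (1.38) were higher. Lower in ΔflgE were the upstream flanks of fljM (-2.62), CCNA_01529 (-2.46), fljJ (-2.31), fljN (-2.07) and CCNA_02286 (-1.15), and the downstream flanks of fljK (-2.44), CCNA_01529 (-2.33), fljO (-1.93), fljM (-1.76) and CCNA_00351 (-1.74). The largest edgeR QL, BH-adjusted p among them were 0.0447 for CCNA_00351, 0.0376 for CCNA_02286 and 0.0109 for CCNA_02146. The call of CCNA_00351 was lost without any WT or ΔflgE replicate or ΔmotB replicate 2 (adjusted p up to 0.295). That of CCNA_02286 was lost without ΔflgE replicate 1 or 3 or any ΔmotB replicate (up to 0.226), and that of CCNA_02146 without ΔflgE replicate 3 or ΔmotB replicate 1 or 3 (up to 0.127). With 200-nt flanks the upstream call of fljL was lost (log2 0.07, adjusted p = 0.911).

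Reads opposite genes, which the gene features do not hold, rose in ΔflgE over WT at 5 genes. Opposite CCNA_00944, a gene near flgE, they went from 0.752 to 5.84 CPM (log2 2.76; edgeR QL, BH-adjusted p = 0.000255), and opposite flgD from 3.18 to 7.12 CPM (1.15; 0.019). Opposite fljL they went from 4.40 to 10.3 CPM (1.20; 0.0023), opposite CCNA_02668 from 1.96 to 5.20 CPM (1.39; 0.034) and opposite CCNA_00958 from 5.81 to 12.7 CPM (1.09; 0.019), each with 3 of 3 libraries higher. Flanks of flgD and fljL on their own strand rose too, and the share of reads given to the wrong strand was not measured. The windows opposite CCNA_02668 follow the downstream flank of flbY on the same strand, so read-through from flbY cannot be told apart.

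Flagellin genes moved apart in ΔflgE: reads beside fljL rose and those beside fljK, fljM and fljO fell. On its downstream side fljL lay 3.47 (SE 0.19) above the mean of the other 4 flagellin flanks on the log2 scale, which was -1.74, but this restates the pattern, and how reads shared between near-identical flagellin genes were counted is not given, so their part in it cannot be told apart from a change in RNA. A single ΔflgE library does not account for it, since the smallest change of a called downstream flank was 1.45 in size, that of fljM without ΔflgE replicate 3. A biological explanation is open and untested here: in textbook accounts FlbT shortens the life of fljK messenger RNA until the hook is complete, and FlgE is the hook protein while MotB is not needed to build a hook.

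Reads beside rod, ring and hook genes rose in ΔflgE over WT. Within 10 kb of flgE (median log2 1.68 over 4 of 4 stretches that rose) an effect of the deleted segment on adjacent DNA and a regulatory response cannot be told apart, because no group lacks the hook protein with flgE in place. More than 100 kb away, reads summed over all 7 stretches of the list, with no low-count filter, were at 13.7 to 14.6 CPM per library in ΔflgE, 3.01 to 5.78 in WT and 5.32 to 6.49 in ΔmotB (log2 1.74, SE 0.27, over WT and 1.27, SE 0.09, over ΔmotB). This argues against an effect limited to adjacent DNA for these stretches as a set. The sum includes the flbY, flgF and flgH stretches called above, so it is not independent of those calls, and its limit was set after values were seen. Of these 7 stretches, 6 were higher in ΔflgE than in WT and 7 were higher than in ΔmotB. They held few reads, 13 to 32 per WT library, and 0 flanks of the list passed singly over all genes against ΔmotB (edgeR QL, BH-adjusted p = 0.0668 as flgF, 0.147 for flgH and 0.496 for flbY), with flbY also higher in ΔmotB than in WT (log2 1.37, unadjusted p = 0.017). The wider upstream flank of CCNA_02146, which contains the flgH flank, did pass (log2 1.61, edgeR QL, BH-adjusted p = 0.0109). That call was lost without ΔflgE replicate 3 or ΔmotB replicate 1 or 3. Flanks at flgB and flgC, about 59 kb away, were not called (log2 -0.13 and -0.46), and a response of flagellar genes to a missing hook, known from textbook accounts of the flagellar hierarchy, is open and was not tested.

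Gene features that fell in both mutants numbered 9, and 0 rose in both. Chance spread between the 3 shared WT libraries would give a covariance near the variance of the WT mean, 0.0134 on log2 CPM with a prior count of 2. The covariance of fitted fold changes is on another measure, so only the simulated values compare directly with the observed one. Simulations gave 0.0165 to 0.0213, and 0.0374 was observed. This argues against that spread as the whole source, though part may come from it. A deviation common to all 3 WT libraries enters neither the variance nor the simulations, so the shared controls are left open as a source. A strain background of WT that differs from that of both mutants cannot be told apart from a response to the loss of motility, because each group has its own strain name, and the 9 features leave both open. Among 100 assignments of the 9 libraries to 3 groups, 2 gave at least 9 shared calls, the real one included, and the other gave 29. That other assignment may reflect a structure of the samples other than the groups.

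Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05. In ΔflgE against WT, the real split alone (1 split) reached its value for gene and RNA features (42, highest other 0), upstream flanks (10, other 0), downstream flanks (21, other 0) and downstream lists (2, other 0), and 2 splits did for upstream lists (1, other 1). In ΔmotB against WT, 1 split reached the value for gene features (16, other 0), upstream flanks (1, other 0) and downstream flanks (10, other 0), and all 10 did for lists upstream (0, other 1) and downstream (0, other 0). Between the mutants, 1 split reached it for gene and RNA features (36, other 15), upstream flanks (11, other 8), downstream flanks (13, other 9) and downstream lists (2, other 1), and 6 did for upstream lists (1, other 1).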

How the results depend on the processing

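The counts of changed flanks, the tests on downstream flanks and those with RNA features left out, factors from flanks or other flank widths were chosen after the data were seen. Of 385 comparisons of main results 334 stayed the same, 21 were weaker, 30 stronger and 0 reversed. Of 1753 comparisons of other results 1664 stayed the same, 87 were weaker, 1 stronger and 1 reversed. A count within 1.5 times the main one was labelled the same. A single value called in neither fit was also labelled the same, whatever its sign. Single values changed sign in 38 comparisons, the reversed one included. The log2 value upstream of pilA in ΔflgE, for 1, ran from -0.44 to 0.04. Called flanks of named genes kept their call in 1065 of 1150 comparisons. The reversed value was the upstream flank of fljL in ΔflgE, at -0.10 with 200-nt flanks, which take in a window of 101 CPM in WT that lies after flaF. Fewer or more features pass with other filters by construction. The cause of the other differences was not tested.

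Changed gene and RNA features in ΔflgE numbered 42, and 26 with an absolute log2 above 1. In ΔmotB they numbered 16, but 52 with DESeq2, 28 with 2 groups in the fit, 5 with an absolute log2 above 1, and 10 to 28 with 1 library left out. Shared falls numbered 9, and 17 with DESeq2.

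Changed upstream flanks in ΔflgE numbered 10, but 18 with no low-count filter (8 up, 10 down, against 7 up and 3 down) and 6 with a CPM of at least 10 in 3 libraries. Between the mutants they numbered 11, and 6 with that stricter filter. In ΔmotB there was 1, but 3 with RLE size factors, 10 with no low-count filter, 7 with 2 groups in the fit, 3 with RNA features left out, 4 with TMM factors from flanks, 2 with 200-nt flanks, 3 with the nearest window only, and 0 to 7 with 1 library left out.

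Changed downstream flanks in ΔflgE numbered 21, and 10 with the stricter filter. In ΔmotB they numbered 10, but 20 with no low-count filter, 5 with the stricter filter, 4 at an adjusted p under 0.01, 6 with an absolute log2 above 1, and 4 to 19 with 1 library left out. Between the mutants they numbered 13, and 11 to 21 with 1 library left out.

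Called lists on upstream flanks in ΔflgE numbered 1, but 0 with the stricter filter, 0 without the deleted genes and their neighbours, which leaves the rod, ring and hook list too short, and 1 to 2 with 1 library left out. Between the mutants they numbered 1, but 0 with the stricter filter, 3 with no filter, 0 without the neighbours, and 1 to 2 with 1 library left out. In ΔmotB there were 0, and 1 with the stricter filter. On downstream flanks they numbered 2 in ΔflgE (1 with an estimated correlation, 1 with the stricter filter), 2 between the mutants (1 with an estimated correlation), and 0 in ΔmotB (1 with the stricter filter, 0 to 1 with 1 library left out).

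The replicate block, a pairing of libraries by number, gave 38 gene and RNA features, 9 upstream and 19 downstream flanks in ΔmotB, and 7 upstream flanks up and 7 down in ΔflgE. The numbers do not pair WT libraries with those of a mutant. Correlations of residuals for equal numbers were -0.003, -0.093 and -0.048 between WT and ΔflgE, and -0.037, -0.011 and -0.089 between WT and ΔmotB. Between the mutants they were 0.485, -0.017 and 0.331. Of these, 0.485 and 0.331 were the highest of all pairs across groups, so a pairing of some mutant libraries is left open. Not every library correlated best with its own number.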

Other observations

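The tests on downstream flanks and on reads opposite genes were chosen after the data were seen.

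Gene groups outside the flagellum and the pili gave 0 calls as lists in camera, in either mutant and on either side, with 0 called by an estimated correlation as well. Cell cycle regulators, which time replication and division, had 1 of 22 upstream flanks that rose in ΔflgE (sciP) and 1 of 28 downstream flanks that fell in ΔmotB (rcdA), with camera BH-adjusted p of 0.665 and 0.993 in ΔflgE and 0.914 and 0.854 in ΔmotB (upstream, then downstream, as below). Adjusted over the list alone, 1 upstream flank rose and 1 downstream flank fell in ΔflgE, and 1 downstream flank fell in ΔmotB. Genes of ribosomal proteins had 15 of 19 upstream and 17 of 20 downstream flanks higher in ΔmotB than in WT, but 0 called (0.342 and 0.144, at unadjusted p of 0.0231 and 0.00798; 0.665 and 0.993 in ΔflgE), and 0 adjusted over the list alone. Holdfast genes, for the polar adhesin, had 0 of 7 and 0 of 12 called (0.936 and 0.993 in ΔflgE, 0.342 and 0.57 in ΔmotB), with 1 downstream rise in ΔmotB adjusted over the list alone. Genes of cyclic di-GMP, the second messenger of surface life, had 0 of 7 and 0 of 8 (0.665 and 0.993 in ΔflgE, 0.941 and 0.948 in ΔmotB), and 0 over the list alone. Stalk and phosphate genes had 0 of 8 and 0 of 8 (0.665 and 0.645 in ΔflgE, 0.914 and 0.57 in ΔmotB), with 1 downstream fall in ΔmotB adjusted over the list alone.

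Stress, growth and surface genes had 0 flanks called. These were heat shock (5 and 6 flanks tested; camera BH-adjusted p of 0.665 and 0.993 in ΔflgE, 0.914 and 0.995 in ΔmotB), general stress (4 and 5; 0.936 and 0.993, 0.914 and 0.59), the SOS response (4 and 4; 0.936 and 0.993, 0.983 and 0.872), and cell division (9 and 10; 0.665 and 0.993, 0.941 and 0.854). DNA replication (5 and 7; 0.747 and 0.993, 0.941 and 0.995), the S-layer (6 and 6; 0.936 and 0.993, 0.914 and 0.995), and respiration with ATP synthase (8 and 6; 0.936 and 0.993, 0.941 and 0.995) also had 0. Adjusted over the list alone, 1 upstream flank fell in ΔflgE for heat shock and 1 for DNA replication, and 0 elsewhere. Chemotaxis genes had 1 upstream flank, too few for camera, and 3 downstream flanks (0.645 and 0.995), with 0 called and 0 over the list alone. Flagellin modification had 2 and 1 tested flanks, too few for camera, with 0 called and 1 downstream fall in ΔflgE adjusted over the list alone. The stator list in ΔflgE had 0 of 2 downstream flanks called, and 2 fell adjusted over the list alone.

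Reads opposite hfsD, a gene of holdfast synthesis, fell in ΔflgE from 23.9 ± 3.81 to 12.3 ± 1.03 CPM (log2 -0.96; edgeR QL, BH-adjusted p = 0.000905, 3 of 3 libraries lower) and were at 27.6 ± 1.64 CPM in ΔmotB. Reads opposite CCNA_01928 fell in ΔmotB from 17.0 ± 4.52 to 8.06 ± 0.961 CPM (log2 -1.05; edgeR QL, BH-adjusted p = 0.00964, 3 of 3 libraries lower). Over all genes, edgeR called reads opposite 5 genes up and 2 down in ΔflgE, and 0 up and 1 down in ΔmotB, among 2199 tested, with 168 and 161 at an unadjusted p under 0.05 in either direction. On the first principal component, with 31.0% of the variance, ΔflgE replicate 1 lay at 18.4 and replicates 2 and 3 at 7.89 and 8.13.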
